A study of Arabidopsis thaliana with 406 samples.

How the data were processed

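RNA sequencing of 406 Arabidopsis thaliana libraries was analysed. Every hybrid has Col-0, the accession of the reference genome, as 1 parent and 1 of 96 other natural accessions as the other. By descent the 96 F1 hybrids thus differ from each other in the accession genome alone. Their libraries also differ in batch and in the state of circadian clock genes. Each tissue has 96 accession libraries, 96 hybrid libraries and 11 Col-0 libraries, 1 in each of 11 batches. Per the labels' protocols, seedlings grew on sucrose medium under long days, and RNA came from the shoot apex at 6 days after sowing or from the first true leaf at 15 days. Each accession and each hybrid has 1 library per tissue, so the cross is the replicate, and the p-values measure the spread between crosses and between the Col-0 libraries of different batches. The labels do not say how many plants went into a library.

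Gene counts were deposited by the authors as whole numbers for 32833 genes. Per the submitters' processing notes, fastp 0.20.0, HISAT2 2.1.0, featureCounts and the genome build TAIR10 were used. The settings of each step, the version of the counting program and whether counting used the strand are not given in the sources used here, so reads of overlapping and antisense genes cannot be assigned with certainty. Reads shared between close copies are also uncertain, which concerns the LHCB1 genes, the RBCS genes, the ribosomal protein genes, AOP3, ESM1, JAL33 and HSD2. The authors also deposited a matrix named as TPM. Its columns sum to between 0.780 and 1.38 times the total of TPM values, so these values are treated as a score. They are score values as deposited by the authors, whose steps after TPM are not given in the sources used here, and they were used only in an alternative. Gene symbols came from an annotation of TAIR10.1, which matched 32548 of the 32833 identifiers. Because that build differs from the authors' build, no coordinates are given.

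Total counts per library ranged from 14696379 to 37110786, with a median of 21631045. The deposited counts carried less difference between batches than chance gives. The median F statistic of the batch term over genes was 0.0505 in the apex and 0.0982 in the leaf, against 0.937 for unrelated batches and 1.17 and 0.997 after the batch labels were shuffled within the same libraries. No source used here names a batch adjustment. Only 139 of 20467 genes in the apex and 264 of 19632 in the leaf had an F above 0.937. These values argue against counts left unadjusted for batch. After an adjustment before deposit, the spread between libraries is narrower than that of raw counts and the p-values are too small. No pair of libraries held identical values, and the highest correlation between a pair was 0.989 in the apex and 0.987 in the leaf.

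Changes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr with a minimum count of 10) in R 4.3.3, in 1 fit per tissue over the 3 classes with batch as a covariate, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The mid-parent is the mean of the accession and Col-0 classes on the log2 scale. A gene outside both parents passed the test against accessions and against Col-0 in the same direction. A joint fit of all 406 libraries, with batch within tissue, compared leaf with apex in hybrids and tested whether the departure from the mid-parent differs between tissues. Its normalised counts (CPM, scaled to library size) are scaled over both tissues and differ from those of the fits per tissue. Tissue and age change together in this design. Values per class are mean CPM ± SD and log2 differences are ± SE.

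Gene lists were fixed before the data were examined: 22 lists of 418 genes, of which 417 were in the counts. AOP2 was not analysed here. The lists are mitotic cell cycle, DNA replication, leaf growth regulators, shoot meristem and boundary, leaf polarity, photosynthesis light reactions, Calvin cycle, chlorophyll synthesis and greening, cytosolic ribosome and its assembly, salicylic acid and defence, circadian clock, auxin and cell expansion, cold and drought response, heat and protein folding, flowering time, anthocyanin and flavonol, aliphatic glucosinolate, senescence and sugar starvation, stomatal lineage and guard cells, trichome and epidermis, vascular, and root. Each was tested with camera (limma 3.58.1, preset correlation of 0.01, adjusted over the lists) and again, as also planned, with an estimated correlation between its genes. The rule for named genes was also fixed beforehand. For the mid-parent comparison it takes the 12 largest changes each way among genes past the threshold with a mean of at least 5 CPM, a symbol and the same direction in at least 64 of 96 crosses. For accessions against Col-0 and for leaf against apex it takes the 8 largest each way under the same CPM and symbol rules. It also takes up to 4 members of each list with the smallest p, and FLC and FRI.

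Tracking of the accession by its hybrid was measured per gene as the Pearson correlation over 96 crosses of batch-centred log2 CPM (prior count 2). Relations across crosses used 100000 permutations within batches, counting departures either way. The clock position of a library is its score on the leading principal component of the 18 clock genes, which held 89.6% of their variance over accessions and hybrids in the apex and 70.6% in the leaf. Accession and hybrid of a cross pair by their label. Their deviations from the class means correlated above 0.1 in 96 of 96 crosses in both tissues, from 0.41 to 0.68 in the apex and from 0.17 to 0.75 in the leaf. Each apex hybrid correlated best with its own accession in 96 of 96 crosses, and each leaf hybrid in 93 of 96, the exceptions being Bs-1, Uod-1 and Ka-0.

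The alternatives were other scalings (DESeq2 size factors, library size only), other filters, DESeq2 1.42.0, no batch term, each batch left out, the cross or genotype as replicate block in limma-voom, the arithmetic mid-parent per cross (pseudocount of 1 CPM), the rescaled TPM values (pseudocounts of 1 and 0.1), a fold change of at least 1.2, fry in place of camera, and rank correlation. Added after the data were examined were the leading 2 clock components as covariates, the leaf without those 3 crosses, limma-voom without the block, and the lists of the joint fit with the members tested in both tissues alone. The procedures were also run on simulated data, after the main fit had been made. With 50 genes changed 1.2-fold, the mid-parent test recovered 45 in the apex and 47 in the leaf, the test of F1 against accessions 50 and 50, that of F1 against Col-0 8 and 18, and that of accessions against Col-0 20 and 18. At 1.5-fold each recovered 50. In these tests every simulated gene had a dispersion of 0.03, and accessions did not differ from each other. Genes with a wider spread would be recovered less often. With 200 genes tracking their accession, 199 and 194 were recovered. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.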

Results

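Gene expression was measured by RNA sequencing in Arabidopsis libraries from 96 natural accessions, the 96 F1 hybrids of each with Col-0, and Col-0 itself. The shoot apex was taken 6 days after sowing and the first true leaf at 15 days. In each tissue 96 hybrids and 96 accessions stand against 11 Col-0 libraries, 1 per batch. The series title names photosynthetic cell number and the heterosis of leaf size. The comparisons therefore ask which genes leave the level midway between the parents in hybrids, whether they do so alike in apex and leaf, and whether cell cycle genes in the apex vary with photosynthesis genes in the leaf across crosses. In the apex the leading principal component held 15.0% of the variance and separated the classes (R² = 0.92). In the leaf the leading component held 17.2% (R² = 0.21). The next held 9.74% and set accessions apart from hybrids and Col-0 but not these from each other (R² = 0.85).

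In the shoot apex the accessions had far lower cold and drought transcripts than Col-0. Single genes of glucosinolate metabolism and of the morning clock were far higher, but neither the glucosinolate list (adjusted p = 0.76) nor the clock list (0.97) passed camera. RD29A (AT5G52310), a marker of the cold and drought response, averaged 88.1 ± 83.4 CPM in accessions (SD, n = 96) and 673 ± 235 in Col-0 (n = 11), a log2 difference of -3.05 ± 0.23 (SE, adjusted p = 3.2e-26). COR15B and COR15A, which protect chloroplast proteins in the cold, differed by -4.41 ± 0.31 and -3.24 ± 0.26, and the dehydration-induced KIN2 by -3.46 ± 0.19. ESP (AT1G54040), which directs glucosinolate breakdown to nitriles, stood at 1149 ± 1026 CPM in accessions and 17.4 ± 25.7 in Col-0 (6.28 ± 0.98, adjusted p = 2.4e-08). AOP3, a glucosinolate side-chain enzyme, was higher by 6.59 ± 1.89, and NSP4, a nitrile-specifier protein, by 3.23 ± 0.26. LHY and CCA1, transcription factors of the morning clock, were higher by 4.57 ± 0.85 and 2.68 ± 0.49. Apex Col-0 libraries sat toward 1 end of the clock component (median -8.51, with crosses from -9.95 to 10.1). With clock covariates CCA1 turned (-0.0856), largely by construction. FLC (AT5G10140), a repressor of flowering, was higher by 2.66 ± 0.56, while the difference of its activator FRI did not pass (-0.36 ± 0.18, adjusted p = 0.091).

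Of 20467 genes tested in the apex, 9485 differed between accessions and Col-0, 5076 higher and 4409 lower in accessions (library size only: 3933 and 5704, limma-voom with the block: 4308 and 4946). Past 4-fold, 455 were higher and 178 lower. Of 15 cold and drought genes 11 were lower (mean log2 difference -1.98, camera adjusted p = 6.3e-11), and adjusted p = 0.040 with an estimated correlation. Of 19 auxin and cell expansion genes 15 were higher and 1 lower (16 and 1 adjusted over the list alone, p = 9.5e-08), and adjusted p = 0.063 with an estimated correlation. Other lists passed camera, but with an estimated correlation their adjusted p ranged from 0.28 to 0.89. They were Calvin cycle (15 of 20 higher), ribosome (19 of 31 higher, 2 lower), photosynthesis light reactions (18 of 51 higher, 3 lower), vascular (5 of 8 higher, 1 lower), leaf growth regulators (3 of 28 higher, 14 lower), anthocyanin (6 of 14 lower) and mitotic cell cycle (6 of 36 lower). Under clock covariates 5 of these calls ended, Calvin cycle (adjusted p = 0.22), photosynthesis and mitotic cell cycle (both 0.82), vascular (0.42) and leaf growth regulators (0.062), while senescence newly passed (4 of 8 lower, 0.033) but not with an estimated correlation (0.50). For 4 lists, none past camera, the median, the mean and the test differed in sign.

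In the leaf single cold transcripts were low in accessions, but the cold list did not pass with an estimated correlation (adjusted p = 0.97) or with clock covariates (0.54). Single glucosinolate genes were high, but their list did not pass camera (8 of 13 higher, adjusted p = 0.052). GolS3, a galactinol synthase, differed by -5.70 ± 0.47 and the dehydrin LTI30 by -4.15 ± 0.54, while RD29A averaged 359 ± 459 CPM in accessions and 2339 ± 2370 in Col-0 (-2.96 ± 0.50, adjusted p = 2.4e-07). MAM3 (AT5G23020), which elongates glucosinolate side chains, stood at 66.3 ± 56.6 CPM against 1.82 ± 2.21 (5.26 ± 0.72, adjusted p = 2.8e-10). ESP stood at 1865 against 57.2 (5.23 ± 0.80), and the jacalin lectin JAL33 at 19.1 against 0.0884 (7.81 ± 1.04). AOP3 had 0 counts in all 11 Col-0 libraries and 12.5 CPM in accessions, at least 1162-fold higher over a floor of 3 counts in the group. FLC was higher by 6.64 ± 1.34 and FRI lower by 0.59 ± 0.16. PR1, a marker of salicylic acid defence, was higher by 4.52 ± 1.43 with a wide spread between accessions (16.2 ± 38.8 CPM). Of 19632 genes tested, 10470 differed, 5805 higher and 4665 lower (limma-voom with the block: 4845 and 5393), and 547 and 254 past 4-fold. Under clock covariates 6474 differed. Of 20 Calvin cycle genes 16 were higher (17 adjusted over the list alone, camera adjusted p = 3.1e-06). Of 15 cold genes 10 were lower and 1 higher (p = 1.9e-04), but both lists had adjusted p = 0.97 with an estimated correlation. Both calls ended with clock covariates, with 9 Calvin cycle genes higher and 1 lower (p = 0.063) and 2 cold genes higher and 4 lower (p = 0.54).

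Hybrids rose above the mid-parent in the shoot apex for cell division and chlorophyll synthesis genes and fell below it for cold, boundary and vascular genes. With an estimated correlation only the chlorophyll list passed (adjusted p = 0.028), while the adjusted p of the other 4 lists ranged from 0.13 to 0.32. For the cold genes Col-0 was the high parent. Against accessions, with clock covariates, 4 of 15 cold genes were higher and 3 lower in hybrids (camera adjusted p = 0.24). The cyclin CYCA2;3 (AT1G15570) averaged 51.3 ± 5.70 CPM in hybrids, 42.5 ± 6.26 in accessions and 39.9 ± 4.69 in Col-0, a log2 change of 0.32 ± 0.04 (adjusted p = 5.0e-13, above the mid-parent in 89 of 96 crosses). TPX2, a spindle assembly factor, rose by 0.28 ± 0.05 and AUR2, an Aurora kinase, by 0.27 ± 0.05. CHLM (AT4G25080), which methylates Mg-protoporphyrin, rose by 0.25 ± 0.03 (395 ± 31.3 CPM against 358 and 310, in 96 of 96 crosses). The Mg-chelatase subunits CHLI1 and CHLD rose by 0.18 ± 0.02 and 0.19 ± 0.02, and CAO, which makes chlorophyll b, by 0.56 ± 0.08. The light-harvesting gene LHCB1.1 rose by 0.49 ± 0.07 (4646 ± 811 CPM against 3546 and 3096).

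Larger single changes in the apex lay elsewhere. ESM1 (AT3G14210), which favours isothiocyanates over nitriles in glucosinolate breakdown, averaged 250 ± 62.7 CPM in hybrids, 40.5 ± 26.8 in accessions and 102 ± 19.8 in Col-0 (1.97 ± 0.16, adjusted p = 2.1e-23, 95 of 96 crosses). For its low level in accessions, reads of diverged alleles lost on the Col-0 reference stay open as a cause. ESP rose by 2.50 ± 0.48, a size that depends on the log scale since its parents differ many-fold. LOX2, a lipoxygenase of jasmonate synthesis, rose by 1.07 ± 0.23. LHY, a clock gene, rose by 1.57 ± 0.44 but turned with clock covariates (-0.0705), of which it is itself a part. HSD2, a hydroxysteroid dehydrogenase, rose by 1.15 ± 0.37 on the log scale only, since its parents differ many-fold. Cold genes fell, with changes of -1.30 ± 0.16 for RD29A and -1.37 ± 0.23 for COR15B. Other single genes fell too, TCH4, a cell-wall xyloglucan enzyme, by 1.24 ± 0.14, the arabinogalactan protein gene AGP7 by 1.06 ± 0.13, and the wax elongase gene KCS1 by 1.05 ± 0.10. The cytokinin response regulator ARR6 fell by 1.00 ± 0.10, and the brassinosteroid-responsive EXO (AT4G08950) by 0.94 ± 0.10, below the mid-parent in 96 of 96 crosses. KLU, a growth-promoting cytochrome P450 of organ margins, fell by 0.50 ± 0.05. The boundary gene CUC3 fell by 0.57 ± 0.07, the abaxial gene KAN1 by 0.38 ± 0.04 and the sucrose exporter gene SWEET11 by 0.83 ± 0.16.

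In the apex 8071 genes departed from the mid-parent, 3987 higher and 4084 lower (library size only: 3329 and 4543, arithmetic mid-parent: 3313 and 5097, limma-voom with the block: 4624 and 4160), with a median absolute log2 change of 0.18. Past 1.2-fold, 1012 rose and 1533 fell, and past 2-fold 143 and 48. Where parents differ many-fold, a mid-parent on the log2 scale favours large rises. Of 36 mitotic cell cycle genes 28 rose and 0 fell (29 and 0 adjusted over the list alone, mean log2 change 0.16, camera adjusted p = 1.8e-09). The list mean was positive in 84 of 96 crosses and in 10 of 11 batches, but adjusted p = 0.30 with an estimated correlation. Chlorophyll synthesis held (16 of 21 rose, 1 fell, 16 and 3 over the list alone, p = 5.5e-10, positive in 91 crosses), and adjusted p = 0.028 with an estimated correlation, or 0.070 with clock covariates as well. Ribosome genes (23 of 31 rose, p = 3.0e-06), cold and drought (1 of 15 rose, 11 fell, p = 7.1e-06), and shoot meristem and boundary (1 of 14 rose, 9 fell, p = 5.2e-05) passed camera. Leaf polarity (5 of 11 fell, p = 0.032) and vascular (4 of 8 fell, p = 0.032) did too. For these 5 the adjusted p ranged from 0.13 to 0.52 with an estimated correlation. The count of 7 lists is no more than shuffled class labels give, as 25 of 101 arrangements gave as many and the highest gave 11. For each of these 7 lists, tested singly, no shuffle gave a mean change as large, but the same held for 4 lists that did not pass (flowering time, heat, senescence and stomatal lineage).

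The remaining lists did not pass in the apex. Closest were stomatal lineage (6 of 11 rose, 1 fell, p = 0.099), heat and protein folding (4 of 5 fell, p = 0.092, or 0.019 with clock covariates, and then 0.12 with an estimated correlation), senescence (2 of 8 rose, p = 0.11) and aliphatic glucosinolate (2 of 13 rose, 6 fell, p = 0.18). At p = 0.41 stood anthocyanin (2 of 14 rose, 1 fell), auxin (4 of 19 rose, 2 fell), Calvin cycle (6 of 20 rose, 2 fell), DNA replication (1 of 28 rose, 6 fell), flowering time (2 of 12 rose) and leaf growth regulators (4 of 28 rose, 7 fell). Photosynthesis light reactions (11 of 51 rose, 5 fell, p = 0.46), root (2 of 4 rose, p = 0.48) and clock (6 of 18 each way, p = 0.64) followed. Salicylic acid (3 of 21 each way, p = 0.74) and trichome (1 of 6 each way, p = 0.79) came last. The median, mean and test differed in sign for glucosinolate (median -0.16, mean 0.18), clock, growth regulators, photosynthesis (median -0.01, mean 0.03) and salicylic acid.

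In the true leaf the cell cycle moved the other way, and carbon fixation and glucosinolate genes rose. None of these lists passed with an estimated correlation (adjusted p = 0.57), and the Calvin cycle call ended with clock covariates (p = 0.79). The glucosinolate list did not differ detectably between hybrids and accessions (median 0.09, mean -0.06, camera adjusted p = 0.42), Col-0 being the low parent. CYCB1;4 (AT2G26760), a mitotic cyclin, averaged 1.09 ± 0.91 CPM in hybrids, 1.95 ± 1.80 in accessions and 7.12 ± 10.5 in Col-0 (-1.82 ± 0.21, adjusted p = 7.0e-13). The mitotic kinase gene CDKB2;1 averaged 1.55 ± 0.62 against 2.23 and 2.41 (-0.59 ± 0.11), and the cytokinesis kinesin HINKEL fell by 0.73 ± 0.13. Nucleolar genes of ribosome assembly fell too, nucleolin NUC1 by 0.51 ± 0.08, the pseudouridine synthase CBF5 by 0.67 ± 0.11 and NOP56 by 0.53 ± 0.09 (90 of 96 crosses below the mid-parent). RCA (AT2G39730), the activase of rubisco, rose to 17320 ± 2378 CPM against 16590 ± 2461 in accessions and 11502 ± 1711 in Col-0 (0.33 ± 0.04, adjusted p = 9.9e-11, 94 of 96 crosses). The Calvin cycle regulator CP12-2 rose by 0.40 ± 0.07 and phosphoribulokinase, PRK, by 0.23 ± 0.04. MAM3 rose by 2.28 ± 0.37 (93 crosses), ESM1 by 1.62 ± 0.22 (734 ± 210 CPM against 112 and 584, 92 crosses) and CYP83A1, of the glucosinolate core pathway, by 0.52 ± 0.12. The size for MAM3 depends on the log scale, since its parents differ many-fold. For the low accession level of ESM1, lost reads of diverged alleles stay open. The expansin gene EXPA8 rose by 1.13 ± 0.22 and FRO7, the ferric reductase of chloroplasts, by 0.99 ± 0.16. EXPA16, another expansin gene, fell by 2.62 ± 0.38, the germin-like GER3 by 1.75 ± 0.25, LTI30 by 1.54 ± 0.38, RD29A by 1.31 ± 0.34 and the epidermal PDF1 by 1.16 ± 0.14. JAL33, ESP and FLC rose on the log scale (2.24 ± 0.60, 1.28 ± 0.36 and 2.27 ± 0.77) but lay below the arithmetic mid-parent (-0.31, -0.29 and -0.13).

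In the leaf 7808 genes departed from the mid-parent, 4113 higher and 3695 lower (library size only: 3122 and 4430, arithmetic mid-parent: 4604 and 6058), with a median absolute log2 change of 0.25. With 2 clock components as covariates 4382 did, 2197 higher and 2185 lower. Past 1.2-fold, 1716 rose and 2032 fell, and past 2-fold 182 and 146, where the log2 scale again favours rises. Of 34 cell cycle genes 0 rose and 22 fell (the same adjusted over the list alone, mean log2 change -0.37, camera adjusted p = 3.7e-06), and the list mean was negative in 84 of 96 crosses and in 10 of 11 batches. Of 31 ribosome genes 0 rose and 22 fell (24 over the list alone, p = 4.9e-10). Of 13 glucosinolate genes 10 rose (11 over the list alone, p = 6.8e-04) and of 15 cold genes 8 fell (9 over the list alone, p = 0.0016). Of 20 Calvin cycle genes 10 rose (p = 0.0077) and of 51 photosynthesis genes 14 rose and 1 fell (p = 0.032). With an estimated correlation none passed (adjusted p = 0.57 to 0.66). Shuffled class labels gave as many as 6 lists in 20 of 101 arrangements, at most 11. Tested singly, the mean change of 5 of these 6 lists exceeded every shuffle, and that of photosynthesis was reached in 9 of 101. Every shuffle was also exceeded by 4 lists that did not pass (anthocyanin, clock, flowering time and growth regulators). With 2 clock components as covariates the Calvin cycle (4 of 20 rose, 4 fell, p = 0.79), photosynthesis (1 each way, p = 0.93) and cold lists (0 each way, p = 0.75) no longer passed. Cell cycle (19 fell, p = 5.4e-12), ribosome (24 fell, p = 3.6e-14) and glucosinolate (6 rose, p = 9.8e-05) still did. With these covariates 4 further lists passed: DNA replication (1 of 27 rose, 12 fell, p = 2.1e-07), salicylic acid (7 of 27 fell, p = 4.5e-05), stomatal lineage (1 of 10 rose, 7 fell, p = 0.0077) and chlorophyll (1 of 21 rose, 7 fell, p = 0.012). None of these 7 passed with an estimated correlation (adjusted p = 0.065 to 0.42). The clock list is left out here because its own genes make up the covariates. Col-0 libraries sat toward 1 end of the clock component (median -6.29, range -11.4 to -2.63, with crosses from -6.94 to 5.50).

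Without those covariates the other lists did not pass in the leaf. Closest were salicylic acid (4 of 27 fell, p = 0.051), DNA replication (1 of 27 rose, 5 fell, p = 0.16), leaf polarity (5 of 11 rose, p = 0.19), senescence (4 of 9 rose, 1 fell, p = 0.19) and growth regulators (2 of 23 rose, 7 fell, p = 0.21). At p = 0.30 stood anthocyanin (3 of 10 fell), flowering time (2 of 12 rose) and trichome (1 of 4 rose, 2 fell). Stomatal lineage (1 of 10 rose, 2 fell, p = 0.37) and meristem (2 of 6 rose, p = 0.41) followed. At p = 0.46 stood chlorophyll (3 of 21 rose, 8 fell), clock (7 of 18 rose, 9 fell) and vascular (2 of 8 rose, 4 fell). Auxin (6 of 20 rose, 2 fell, p = 0.56) and heat (1 of 8 each way, p = 0.81) came last. Sign differed between median, mean and test for the clock (median -0.04, mean -0.15, test upward) and heat lists. No root gene list could be tested in the leaf.

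**Figure D1:**
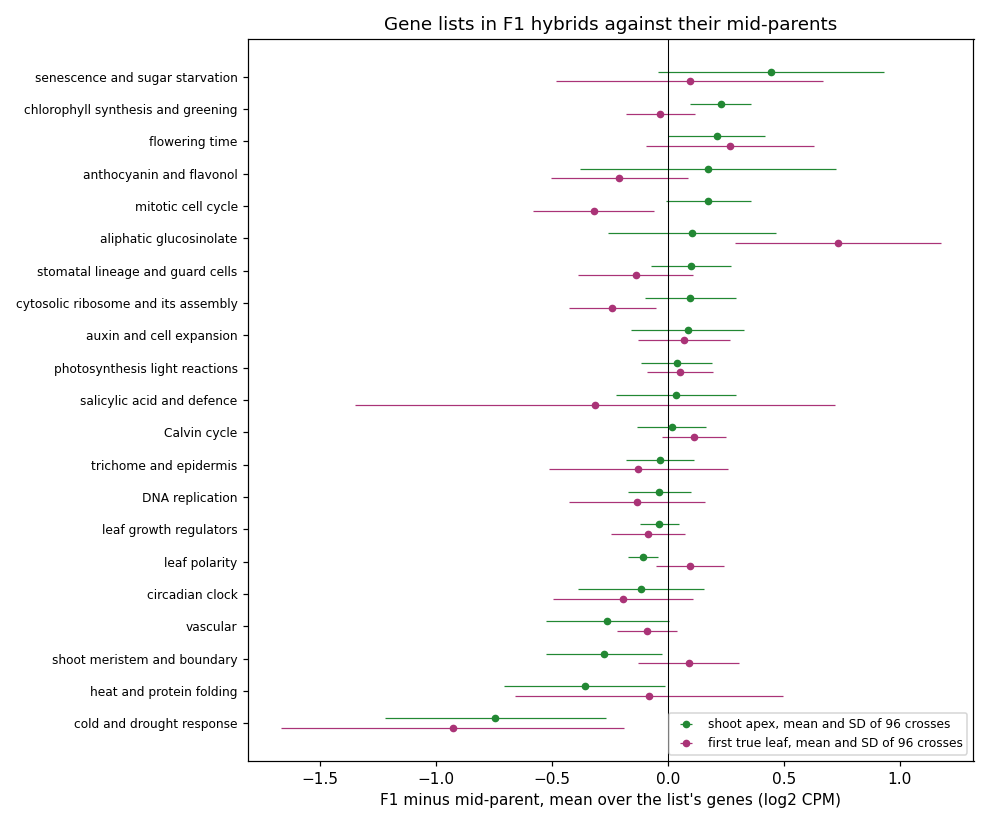
Mean departure of hybrids from the mid-parent for each gene list in apex and leaf (log2, mean and SD of 96 crosses). The root list was not tested in the leaf.

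**Figure D2:**
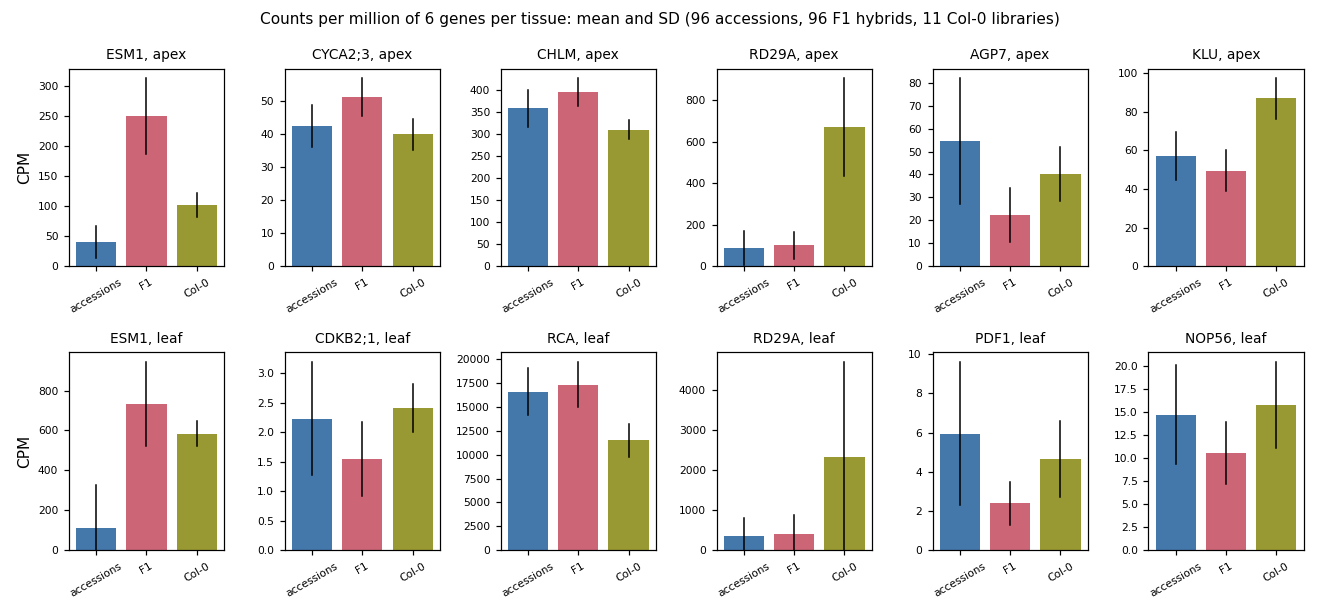
Normalised expression (CPM) of named genes in hybrids, accessions and Col-0 of both tissues (mean and SD, n = 96, 96 and 11).

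Against their accessions, hybrids had higher counts of ESM1, of glucosinolate breakdown (2.64 ± 0.10 in the apex, adjusted p = 1.0e-59, and 2.90 ± 0.16 in the leaf, adjusted p = 1.1e-40) and of HSD2, of steroid metabolism (3.25 ± 0.30 and 2.85 ± 0.29). Both were lower in accessions than in Col-0, and reads of diverged accession alleles lost on the Col-0 reference stay open as a cause. Cell division genes again parted by tissue without any Col-0 library in the contrast. CYCA2;3 rose by 0.27 ± 0.03 in the apex, while CDKB2;1 fell by 0.53 ± 0.09 and NOP56, of ribosome assembly, by 0.48 ± 0.07 in the leaf. In the apex TMM, a receptor of the stomatal lineage, rose by 0.41 ± 0.04 and the anthocyanin regulator TT8 by 1.17 ± 0.14, while the boundary gene CUC1 fell by 0.86 ± 0.07. In the apex 13060 genes changed (6000 higher, 7060 lower) and in the leaf 9584 (4169 and 5415). The balance turned with limma-voom, to 7810 higher and 7018 lower in the apex and 6695 and 5889 in the leaf with the block, and to 6925 and 6125, and 5123 and 4398, without it. Of 36 cell cycle genes 31 rose and 1 fell in the apex (the same adjusted over the list alone, camera adjusted p = 2.6e-10, positive in 87 crosses), and adjusted p = 0.28 with an estimated correlation. Of 34 in the leaf 1 rose and 25 fell (26 over the list alone, p = 2.5e-06, positive in 14 crosses), and adjusted p = 0.39 with an estimated correlation. Chlorophyll synthesis genes went 15 up and 1 down in the apex (p = 8.2e-04) and 2 up and 13 down in the leaf (p = 0.0056), and of 27 DNA replication genes in the leaf 2 rose and 18 fell (p = 4.5e-04). Neither these nor the other lists that passed camera here held with an estimated correlation (adjusted p = 0.28 to 0.72).

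Against Col-0, hybrids had low cold response transcripts in the apex, like the accessions. In the leaf the cold list (1 of 15 rose, 10 fell, camera adjusted p = 4.3e-05) did not pass with an estimated correlation (0.85) or with clock covariates (1 rose, 3 fell, p = 0.44). RD29A fell by 2.83 ± 0.23 in the apex and 2.79 ± 0.51 in the leaf, and KIN2 by 2.67 ± 0.20 in the apex. BMY3, a beta-amylase gene, rose by 2.34 ± 0.36 in the apex, the clock factor RVE8 by 1.25 ± 0.16 in the leaf, and the Calvin cycle gene FBA1 by 0.69 ± 0.10 in the leaf (2199 CPM against 1366). In the apex 6913 genes differed (3514 higher and 3399 lower, with library size only 2565 and 4339) and in the leaf 8971 (4810 and 4161, with library size only 3831 and 4882). Under clock covariates 3915 differed in the leaf, 2133 higher and 1782 lower. Of 15 cold genes 12 fell in the apex (camera adjusted p = 2.1e-13, and adjusted p = 0.012 with an estimated correlation). Of 21 chlorophyll genes 15 rose and 3 fell (p = 3.0e-08, and adjusted p = 0.048 with an estimated correlation, or 0.16 with clock covariates as well). Of 19 auxin genes 10 rose in the apex (11 adjusted over the list alone, p = 3.8e-05), and of 20 Calvin cycle genes in the leaf 13 rose (p = 1.8e-05), neither past the threshold with an estimated correlation (adjusted p = 0.22 and at least 0.85). The leaf Calvin cycle call ended with clock covariates (5 rose, 1 fell, p = 0.10).

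Genes outside both parents in the apex included CHLM above and AGP7, KCS1, TCH4, EXO and CUC3 below, and in the leaf FRO7 above and NOP56, CDKB2;1 and PDF1 below. CHLM, of chlorophyll synthesis, exceeded accessions by 0.14 ± 0.02 and Col-0 by 0.35 ± 0.05, and the cell-wall gene AGP7 fell short of them by 1.28 ± 0.10 and 0.84 ± 0.21. In the apex 1296 genes stood above and 1273 below both (library size only: 923 and 1517), and in the leaf 986 and 913 (644 and 1115). With 2 clock components as covariates the leaf had 373 above and 580 below. If the 2 tests were independent, the lists of higher and lower genes would share 1030 and 1172 genes in the apex and 1021 and 1148 in the leaf. The leaf counts are thus no larger than independent lists give. With 46 hybrids, the same in both contrasts, 1131 stood above and 1132 below in the apex and 748 and 715 in the leaf. With separate hybrids in each contrast the counts were 1093 or 1043 above and 1027 or 1001 below in the apex, and 681 or 688 above and 589 or 685 below in the leaf. Past 1.2-fold from each parent were 194 above and 456 below in the apex, and 183 and 384 in the leaf.

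Between tissues, hybrid leaves had lost cell division and meristem transcripts. Photosynthesis and defence genes were higher in the leaf, but their lists did not pass with an estimated correlation. FRO6, a ferric reductase of green tissue, went from 4.22 ± 1.81 CPM in the apex to 1199 ± 394 in the leaf (8.15 ± 0.12), ACD6, a regulator of salicylic acid defence, from 0.163 to 56.2 (8.36 ± 0.23), and the sugar exporter gene SWEET13 from 0.0263 to 16.5 (9.03 ± 0.14). KLU went from 40.4 ± 8.48 to 0.00895 (-11.72 ± 0.12), and the meristem homeobox gene KNAT1 from 38.5 ± 11.3 to 0.0667 (-9.09 ± 0.11). CYP77B1, a cytochrome P450 gene, stood at 71.6 and 0.00146. Of 21128 genes 19538 differed, 9982 higher and 9556 lower in the leaf. Photosynthesis (51 of 51 higher, mean 1.94, adjusted p = 0.067 with an estimated correlation), the Calvin cycle (20 of 20 higher, 0.096) and salicylic acid and defence (24 of 27 higher, 0.51) no longer passed with that correlation. Mitotic cell cycle (36 of 36 lower, mean -4.94, 0.0084), DNA replication (28 of 28 lower, 0.047), meristem (12 of 14 lower, 2 higher, 0.0084), growth regulators (20 of 28 lower, 5 higher, 0.017) and trichome (5 of 6 lower, 1 higher, 0.039) did pass. Ribosome (31 of 31 lower, 0.096), anthocyanin (13 of 14 lower, 0.20) and cold (14 of 15 higher, 0.51) passed camera but not with that correlation.

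The departure from the mid-parent itself differed between leaf and apex, among others for cell cycle genes, which rose in the apex and fell in the leaf. Leaf minus apex, the departure differed by 2.398 ± 0.48 for MAM3 (adjusted p = 2.2e-05), a size that depends on the log scale since its leaf parents differ many-fold. The departure differed by 1.38 ± 0.18 for EXO (1.2e-10) and by 1.00 ± 0.21 for the cytokinin response gene ARR6. It differed by -1.67 ± 0.29 for LOX2 (1.4e-06) and by -1.50 ± 0.18 for ABCB14, an ABC transporter gene (6.3e-13). Of 21128 genes 5838 differed, 2713 with a higher value in the leaf and 3125 with a lower one. Of 36 cell cycle genes 26 had a lower value in the leaf (29 adjusted over the list alone, mean -0.55, camera adjusted p = 1.1e-13, and adjusted p = 0.044 with an estimated correlation). These genes were low in leaf hybrids, with BUBR1 at 0.417 CPM, TPX2 at 0.602, HINKEL at 0.743 and CYCA2;3 at 2.56. In the meristem list, which fell in the apex, 3 of 14 genes had a higher value in the leaf (mean 0.38, p = 2.3e-05, and adjusted p = 0.017 with an estimated correlation). But STM (0.0292 CPM), CUC2 (0.0312) and KNAT1 (0.0667) were near the floor in leaf hybrids. With the members tested in both tissues alone, a choice made after the result was seen, the meristem call ended (6 genes, mean 0.17, p = 0.086). The cell cycle call stayed (34 genes, mean -0.54, p = 1.2e-13), but adjusted p = 0.081 with an estimated correlation. Ribosome (26 of 31 lower), chlorophyll (15 of 22 lower, 2 higher), glucosinolate (9 of 13 higher) and polarity genes (5 of 11 higher) passed camera, but with an estimated correlation their adjusted p lay between 0.11 and 0.14.

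Hybrid expression followed that of its own accession in nearly every gene. ESP, the nitrile-directing protein, was among the list members that did so most, and the glucosinolate list had a median r of 0.72 in the apex and 0.69 in the leaf. The clock list reached 0.93 and 0.78, cold genes 0.84 in the leaf, and cell cycle genes 0.56 in the apex (36 of 36 past the threshold) and 0.38 in the leaf (28 of 34). ESM1 was an exception in the apex, with r = -0.07 (adjusted p = 0.52), while in the leaf its weak positive correlation (r = 0.28) passed the threshold. Lost reads of its accession alleles stay open as a cause of these low values. In the apex 18796 of 20467 genes (91.8%) correlated positively and 1 negatively, and in the leaf 18718 of 19632 (95.3%) and 2, with medians of 0.52 and 0.59 across genes, which are not independent replicates. With the clock components removed, 18089 and 18067 passed. Inheritance was not separated here from conditions shared by an accession and its hybrid at collection.

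Across crosses, cell cycle departure in the apex did not vary detectably with photosynthesis departure in the leaf (r = -0.063, 95% interval -0.27 to 0.15, permutation p = 0.54, n = 96). By rank rho was -0.013 (p = 0.90), and without the 2 crosses farthest from the median r was -0.050. Within batches r was positive in 4 of 11 and ranged from -0.60 to 0.75, with 7 to 10 crosses per batch. Clock genes, of which LHY and CCA1 mark the morning, differed between crosses of a batch and moved together in an accession and its hybrid. Along the clock component the slope of hybrid on accession was 1.00 (95% interval 0.96 to 1.04) in the apex and 0.86 (0.78 to 0.94) in the leaf. A cross's position in the apex varied with that in the leaf (r = 0.27, p = 0.012, and rho = 0.27, p = 0.012), with r = 0.25 without 2 crosses. Within batches it was positive in 10 of 11, from -0.26 to 0.92. Over these 2 relations the adjusted p are 0.54 and 0.025.

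**Figure D3:**
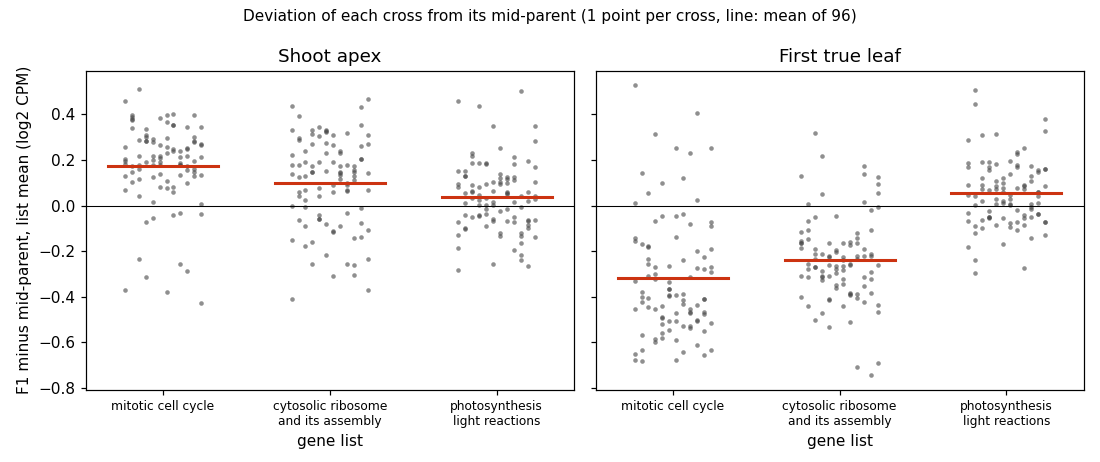
Departure from the mid-parent in each of 96 crosses for cell cycle, ribosome and photosynthesis lists in both tissues (log2, with a line at the mean).

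**Figure D4:**
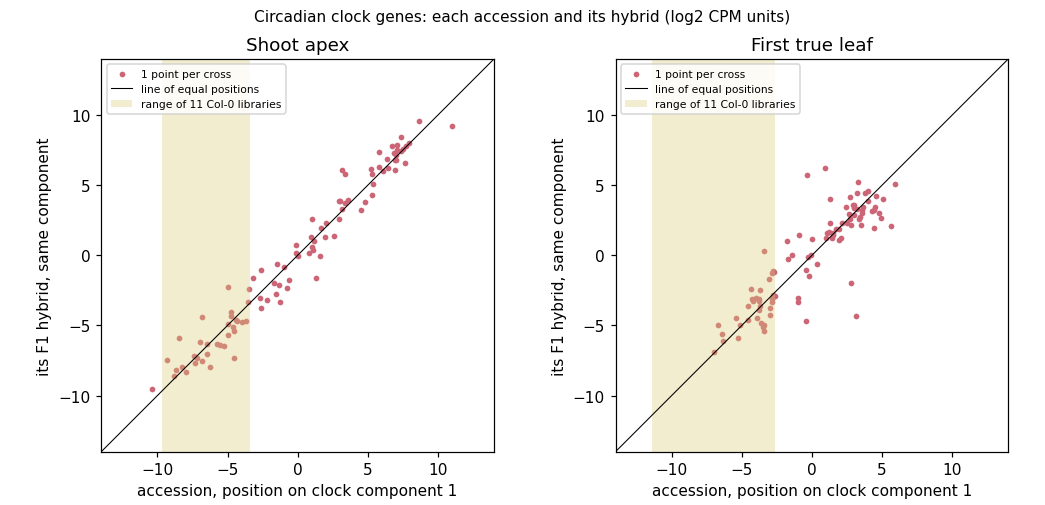
Position on the clock component of each accession and of its hybrid, with the line of equality and the range of the 11 Col-0 libraries shaded.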

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

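The tests against swapped partners, both tests of the clock genes and the test of Col-0 alone were chosen after the result was seen, as were the clock covariates, the shuffles of single list means and the lists of genes tested in both tissues. The other tests were written beforehand. For 4-fold genes the thresholds were written beforehand, but the pattern was then worded as an excess of lower genes, and that wording was dropped once the counts were seen.

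Departures from the mid-parent differed between leaf and apex by a test of the difference itself, for 6 lists and for 17 of the 43 genes with the largest departures. Over all genes tested 5838 of 21128 (27.6%) differed. The 43 were picked by a large departure in a tissue on the same libraries, which favours a difference and a large size of it. Given as leaf minus apex, the mean log2 differences were -0.55 for mitotic cell cycle, -0.35 for ribosome, -0.25 for chlorophyll synthesis, 0.82 for aliphatic glucosinolate, 0.38 for shoot meristem and 0.21 for leaf polarity. With an estimated correlation only cell cycle (adjusted p = 0.044) and meristem (0.017) passed, and ribosome, chlorophyll, glucosinolate and polarity did not (0.11 to 0.14). With the members tested in both tissues alone the meristem call ended (0.086), since most of its genes are barely expressed in the leaf, and cell cycle passed (1.2e-13) but not with an estimated correlation (0.081). Of the 17 genes MAM3 differed most, by 2.398, followed by JAL33 at 2.19 and LOX2 at -1.67. The places of MAM3 and JAL33 hold on the log scale. The leaf parents of MAM3 differ many-fold, and the leaf departure of JAL33 turned with the arithmetic mid-parent (-0.31). Among genes of the cell wall and growth, EXO differed by 1.38, TCH4 by 1.18, EXPA8 by 1.05, ARR6 by 1.00, SRF4 by 1.00, EXPA16 by -1.43, ATPMEPCRB by -1.25 and AIR3 by -1.10. Among transporters and other genes, ABCB14 differed by -1.50, GER3 by -1.49, ProT3 by -0.92, FRO7 by 0.69, ATCTH by -0.62 and J11 by -0.57.

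Chance was tested by other splits of the samples, with 22 random splits beside the real one for genes, since each is a full fit. Only the real split, 1 of 23, gave as many genes in each gene comparison. Chance is thereby excluded for hybrids against accessions and for leaf against apex. In comparisons that use Col-0, the mid-parent among them, a shuffled Col-0 group held mostly different genotypes, while the real one is 1 genotype in 11 libraries. There the splits show only that random groups of libraries do not give such counts. They cannot tell this from the distinctness of any single genotype. Against the mid-parent the real count was 8071 genes in the apex (highest other 6) and 7808 in the leaf (12). Against accessions it was 13060 (1) and 9584 (1), and against Col-0 6913 (30) and 8971 (18). Between accessions and Col-0 it was 9485 (60) and 10470 (19), and outside both parents 2569 (0) and 1899 (2). For genes outside both parents these splits exclude nothing, because shuffled labels empty both contrasts. Independent lists would share 1021 genes above and 1148 below in the leaf, more than the 986 and 913 seen, so chance overlap is not excluded there. On 2641 genes the difference of departures gave 758 genes (highest other 3) and leaf against apex 2445 (highest other 1353, since uneven swaps keep part of the tissue difference). For tracking, 1 of 101 splits gave as many genes, the real one, with 18796 in the apex (highest other 24) and 18718 in the leaf (51). The number of lists past camera is another matter: 25 of 101 splits gave at least the 7 of the apex (highest other 11) and 20 of 101 the 6 of the leaf (11), so chance is not excluded for these counts of lists.

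Cell cycle genes stood above the mid-parent in the apex (0.17 ± 0.03 as 1 value per library) and below it in the leaf (-0.32 ± 0.06). A clock state of Col-0 unlike that of the crosses would shrink the change once 2 clock components are covariates, but the lower ratio of the change with them to that without was 1.15, so the tables argue against it. An unusual level in Col-0 alone would vanish against accessions, but the lower ratio of that change to the mid-parent change was 1.01. A candidate explanation that remains is a hybrid leaf further past cell division at 15 days than its parents' leaves, and it is untested, as is a different share of dividing cells in the dissected apex. The list's camera call did not hold with an estimated correlation in either tissue. With counts adjusted for batch before deposit, as the batch term points to, the errors are too small.

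Clock genes moved in step in an accession and its hybrid. Additive inheritance on the log2 scale calls for a slope near 0.5 of hybrid on accession, and the lowest of the 95% lower bounds was 0.781, which argues against it. Inherited differences also call for positions that go together in apex and leaf, and these did (r = 0.27, p = 0.012), so inheritance that is not additive stays open. Collection of both at a common time of day was held to call for a slope above 0.75 in both tissues, and the lower of the slopes was 0.861. That slope, in the leaf, has a 95% interval of 0.78 to 0.94. It lies below 1, but noise in the 1 library per accession also lowers a slope, so this does not argue against a common time. The sources used here give no collection times, so this explanation stays open. Dominant inheritance from the accession was not tested. The leaf Calvin cycle and photosynthesis changes did not pass once clock components were covariates, so a clock difference between Col-0 and the crosses may account for them.

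Genes over 4-fold apart between accessions and Col-0 could reflect reads of diverged alleles lost on the Col-0 reference. This was held to call for more lower than higher genes in accessions. The larger of the ratios of lower to higher genes was 0.464. Lost reads can only lower a gene in accessions, so they do not account for the higher genes. The ratio does not test the lower genes, 178 in the apex and 254 in the leaf. It also depends on the number of higher genes, which have other causes. For genes that were lower in accessions, HSD2 and ESM1 among them, lost reads stay open. Gene copies that differ between accessions, a biological explanation, were not tested.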

How the results depend on the processing

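Clock covariates, the leaf without 3 crosses, limma-voom without the block and lists of genes tested in both tissues were chosen after the data were examined. Of 90 values under the alternatives planned beforehand 86 lay within 1.5 times the reported count, as did 27 of 33 under the added ones (counted with them is camera with an estimated correlation, planned as a test but not as an alternative) and 110 of 110 without a batch. These counts carry less difference between batches than chance gives. Fits without a batch term or without 1 batch thus cannot show how batch differences in raw counts would act. Beyond 1.5 times, a fold change of at least 1.2 left 2545 genes against the mid-parent in the apex and 3748 in the leaf, since smaller changes are excluded by construction. The lists past the test were 1 in the apex and 0 in the leaf with an estimated correlation, and 11 and 12 with fry. With 2 clock components as covariates the leaf gave 4382 genes against the mid-parent, 3915 against Col-0, 6474 between accessions and Col-0 and 953 outside both parents, and the direction of the leaf photosynthesis list turned (adjusted p = 0.927). In the apex the counts under these covariates lay within 1.5 times, but the genes changed. Of 6913 genes against Col-0 4154 stayed and 17 turned, and of 9485 between accessions and Col-0 6006 and 50. Of 8071 genes against the mid-parent 6366 stayed and 5 turned. The same covariates turned LHY against the mid-parent (-0.0705) and CCA1 between accessions and Col-0 (-0.0856) in the apex, largely by construction, since both genes are part of those components. The arithmetic mid-parent turned HSD2 (AT3G47350) in the apex (-8.34e-04) and JAL33 (-0.31), ESP (-0.29) and FLC (-0.13) in the leaf, by its construction where parents differ many-fold. WRKY53 between leaf and apex turned with limma-voom, with the block (-0.26) and without it (-0.26), and the cause was not tested. With the pairing as replicate block the counts were 8784 in the apex and 9201 in the leaf against the mid-parent, 14828 and 12584 against accessions, 6614 and 8827 against Col-0, 9254 and 10238 between accessions and Col-0, and 2803 and 2648 outside both parents. At this depth, with 11 Col-0 libraries and a dispersion of 0.03, 8 and 18 of 50 simulated 1.2-fold changes against Col-0 were recovered. Small differences from Col-0 are thus missed, more so in genes with a wider spread.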

Other observations

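The labels describe no test of glucosinolate breakdown, and no list of its genes was tested here. But 2 of them, ESM1 and ESP, held large departures on the log2 scale in apex hybrids. ESM1, which favours isothiocyanates, averaged 250 CPM in apex hybrids against 40.5 in accessions and 102 in Col-0, above both parents, and did not follow the accession across crosses (r = -0.07). Lost reads of diverged accession alleles stay open for its low accession level and for this r. ESP, which favours nitriles, lay between its parents instead (746 CPM in hybrids, 1149 in accessions and 17.4 in Col-0) in the apex. Its parents differ many-fold, so the size of its departure depends on the log scale of the mid-parent. MAM3, of glucosinolate synthesis, rose in the leaf by 2.28 ± 0.37 but not detectably in the apex (-0.12 ± 0.33). Its parents too differ many-fold in the leaf, so the size of that rise depends on the log scale.

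Boundary genes fell in the apex, CUC3 by 0.57 ± 0.07, CUC1 by 0.65 ± 0.09 and CUC2 by 0.38 ± 0.07, with the meristem receptor gene CLV1 by 0.23 ± 0.04. In the same apices the stomatal lineage receptor gene TMM rose by 0.40 ± 0.05 and FAMA, which forms guard cells, by 0.17 ± 0.05. The shoot meristem and boundary list passed camera but not with an estimated correlation (adjusted p = 0.13), and the stomatal lineage list, in which 6 of 11 genes rose and 1 fell, did not pass (p = 0.099).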
